A study of Mus musculus with 6 samples.

How the data were processed

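Long-term haematopoietic stem cells (LT-HSC), the most durable stem cells of the blood system, were sorted from mouse bone marrow 2 days after sex steroid ablation (SSA) or after a sham procedure. The animals were males 2 months old, per the labels. Total RNA was labelled with biotin and hybridised to Illumina mouse whole-genome BeadChips, on which each transcript is read by many beads carrying the same probe. Each group had 3 arrays, 6 in all. The labels number the samples but do not say that they came from separate animals, so p-values measure the spread between these samples, which may be technical.

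The deposited raw table holds linear intensity values, 1 value per gene and array, with no background correction and no normalization, per the file headers, which name GenomeStudio 1.8.0. Its rows are gene names rather than probes, so signals of several probes with one name had been combined before deposit. The table also holds a detection score that rises with the signal, which the authors deposited per gene and array. Its values behaved as 1 minus a detection p (Spearman correlation with the signal 0.954 to 0.959 across the arrays), and it was used in that form. The score and the signal did not always go together: on each array 409 to 464 of the rows that were not detected had a signal over the median of the detected rows, and bright genes such as Tgm2 were detected on only some arrays. Detected below means by this score, and a filter on the signal itself was added after the data were examined. The minimum and average signal columns were equal on all 30774 rows. The series matrix, also deposited as intensity on a linear scale, equalled the raw signal minus 1 constant per array, between 126.6 and 138.1, within 0.1. It lacked 7 of the rows and was used as an alternative. No header names the BeadChip or slide of an array, so no batch could be tested. The column headers do number the arrays, and every SSA number comes before every sham number. If that order reflects batches, their effect cannot be told apart from that of SSA in any comparison below.

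Row names were matched to current symbols through the NCBI gene table of assembly GRCm38.p6, used for names only. Of the rows, 15991 matched a current symbol, 5826 matched an older one, 119 matched several and 8838 matched none and kept their own name. After matching, 28888 genes remained, and 3654 rows shared a symbol with another row. Between 35.8% and 37.7% of rows per array had a detection p under 0.05. The median raw signal lay between 132.3 and 145.3, and the median number of beads was 44 on every array. No array pair held identical values. For arrays, their number limits the precision.

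Signals were corrected and normalised with neqc of limma 3.58.1 in R 4.3.3, which fits a normal background and an exponential signal with the help of the detection p, adds an offset of 16, quantile-normalises and takes log2. Rows with a detection p under 0.05 on at least 3 of the 6 arrays were kept, and a gene with several rows was represented by the one with the highest mean, which left 10821 genes. SSA was compared with sham by limma (lmFit and eBayes, group as the only term, two-sided) with Benjamini-Hochberg adjustment, and genes at an adjusted p under 0.05 were called. Fold changes are on the log2 scale after the offset, which understates changes of dim genes. Each value is given as mean ± SD of 3 arrays or as a log2 fold change, SSA minus sham, with its standard error.

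The background fit had a limit. With gene-level rows, neqc estimated a background mean of 168.04 to 204.2 and an SD of 194.91 to 302.65. The signals at which the detection score crosses its middle range gave 126.1 to 137.7 and an SD of 7.4 to 9.05, close to the constants subtracted by the authors. The first setting was kept as planned, and a second one that takes mean and SD from this detection curve was added after the data were examined. It is called the detection-curve setting and its values are printed for named genes and for lists whose median is given where they differ by over 1.5 times. The main setting compresses fold changes of dim genes.

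Before the data were examined, 26 pathway lists and 9 cell type lists were written, together with the tests, the alternatives and the rule for named genes. Lists with at least 5 kept genes were tested with camera at a preset correlation between genes of 0.01, two-sided, adjusted within each family of lists, and called at an adjusted p under 0.05. Camera with an estimated correlation and fry were alternatives. The macrophage list and the stromal, osteoblast and adipocyte list kept 4 genes each and were not tested. Named genes carry a symbol that is not a clone or provisional name. Where fewer than 20 genes pass, the rule names those that pass and then the 10 rises and 10 falls of smallest unadjusted p. It adds up to 4 members of smallest p for each list that was called or had members past the test, the 3 brightest members of each cell type list and a fixed set of steroid, stem cell and cell cycle genes. Some genes that the rule names are not reported here.

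The alternatives were no background correction, normexp by maximum likelihood with an offset of 50, cyclic loess, a median shift per array, the series matrix values, no filter on dim genes, a stricter filter, every row or the mean of rows of a gene, a filter on signal (raw signal over the detection-curve mean plus 3 SD on at least 3 arrays, 10437 genes), other variance models, the replicate number as a block and each array left out in turn. The alternatives written for probes were run on rows that share a symbol. The series matrix values were on a linear scale, so they were quantile-normalised, floored at 0 and put on a log2 scale with an offset of 16. The planned block by BeadChip was not run.

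The tests were tested on simulated data with the means and spreads of these arrays. Of 200 genes changed among 10821, 62% were recovered at a log2 change of 0.5, 80% at 1 and 93% at 2, with 7, 13 and 10 false calls. In this simulation genes varied independently and changes were added after normalisation. It leaves out the compression of dim genes and the correlation between genes, so recovery of real changes may be lower. Camera with the preset correlation called the G2/M list at p under 0.05 in 4% of 100 draws without an effect when its genes were independent. With a correlation of 0.37 between its genes, it did so in 58% of draws. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.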

Results

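The data set held 6 arrays of mouse LT-HSC sorted from bone marrow, 3 taken 2 days after SSA, the surgical removal of the source of sex steroids, and 3 taken after a sham operation. The study asked which transcripts of these stem cells differed early after sex steroid loss. Signal was measured for 28888 genes, of which 10821 were detected on at least 3 arrays. Pearson correlations of log2 signal between arrays ran from 0.963, between SSA 1 and sham 2, to 0.993, between SSA 1 and SSA 2. The first principal component held 50.6% of the variance and did not part the groups cleanly, since sham 1 lay among the SSA arrays at -10.8 and sham 2 lay farthest out at 26.1.

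After SSA, genes of mitosis and of S phase, immediate-early genes and genes of sterol synthesis were lower as groups, and genes known to be higher in aged HSC, ribosomal protein genes, interferon-stimulated genes and genes of HSC identity were higher. These were 8 of 26 pathway lists, called by camera with a preset correlation between genes, at adjusted p from 2.02e-11 to 0.0396. With an estimated correlation none of them was called, at adjusted p from 0.683 to 0.757. The largest median log2 fold change among them was -0.88, for immediate-early genes, and the smallest was -0.023, for sterol synthesis. The direction of each held in the 19 other settings that ran the lists again with the preset correlation.

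The lowest p among falls belonged to Ear6, an eosinophil-associated ribonuclease, at 7.10 ± 0.016 in SSA against 7.38 ± 0.032 in sham (SD, n = 3), a log2 fold change of -0.28 ± 0.024 (SE), SSA minus sham. Its relatives Ear2 and EAR4, the latter a name as given in the data that matched no current symbol, stood at -0.82 ± 0.12 and -0.47 ± 0.053. All 3 signals were low, and with the detection-curve setting the log2 fold changes were -2.11, -2.10 and -2.35. Ear genes have near-identical copies that a probe may not tell apart, so which copy carried the signal is uncertain. In limma, Ear6 did not pass in the main setting, with an adjusted p of 0.464. It passed in 5 of 19 other settings, including the detection-curve setting, with adjusted p across all of them from 0.0311 to 0.998.

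No gene passed an adjusted p of 0.05 in limma, and 852 genes had an unadjusted p under 0.05, where 541.05 would be expected by chance. Of those, 520 were higher and 332 lower after SSA. In 14.6% of genes the 3 SSA arrays lay wholly above or below the 3 sham arrays, where chance gives 10%. Both chance values are averages and do not show how far counts spread when genes vary together. Of the 10 splits of the 6 arrays into 3 and 3, 2 reached 852 genes, the real one and another with 1619. An unmoderated test of each gene called 0, with 782 at an unadjusted p under 0.05, and other settings called between 0 and 2. The number at an unadjusted p under 0.05 was 483 without SSA 1, 534 without sham 3 and 1520 without sham 1. With a median shift per array it was 452, of which 34.7% were higher, against 61.0% in the main setting.

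Among the values that did not pass, the 10 rises of smallest p included Lxn, which encodes latexin, a protein that restrains stem cell number in mouse marrow, at 0.30 ± 0.026 on the log2 scale. Herpud1, a component of endoplasmic reticulum degradation, stood at 0.24 ± 0.027, Cstb, a cathepsin inhibitor, at 0.30 ± 0.041, and Cited2, a transcriptional regulator needed for stem cell maintenance, at 0.65 ± 0.10. The remaining rises were Zfp87, Ccdc90b, Commd7, Gde1, Bhlhb9 and Tsen15, between 0.17 and 0.44, with Zfp87 at 0.28 in the detection-curve setting. The 10 falls of smallest p included, besides Ear6, EAR4 and Ear2, the gene Birc5, an inhibitor of apoptosis that acts in mitosis, at -0.90 ± 0.12, the mitotic kinase gene Pbk at -0.69 ± 0.086 and the histone gene H4c17 at -0.92 ± 0.13. Nasp, a histone chaperone, stood at -0.37 ± 0.055. Angel2, Ostc and Acat2 stood at -0.37, -0.41 and -0.19. For these 20 genes every SSA array lay on one side of every sham array, and adjusted p values lay between 0.464 and 0.483.

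**Figure D1:**
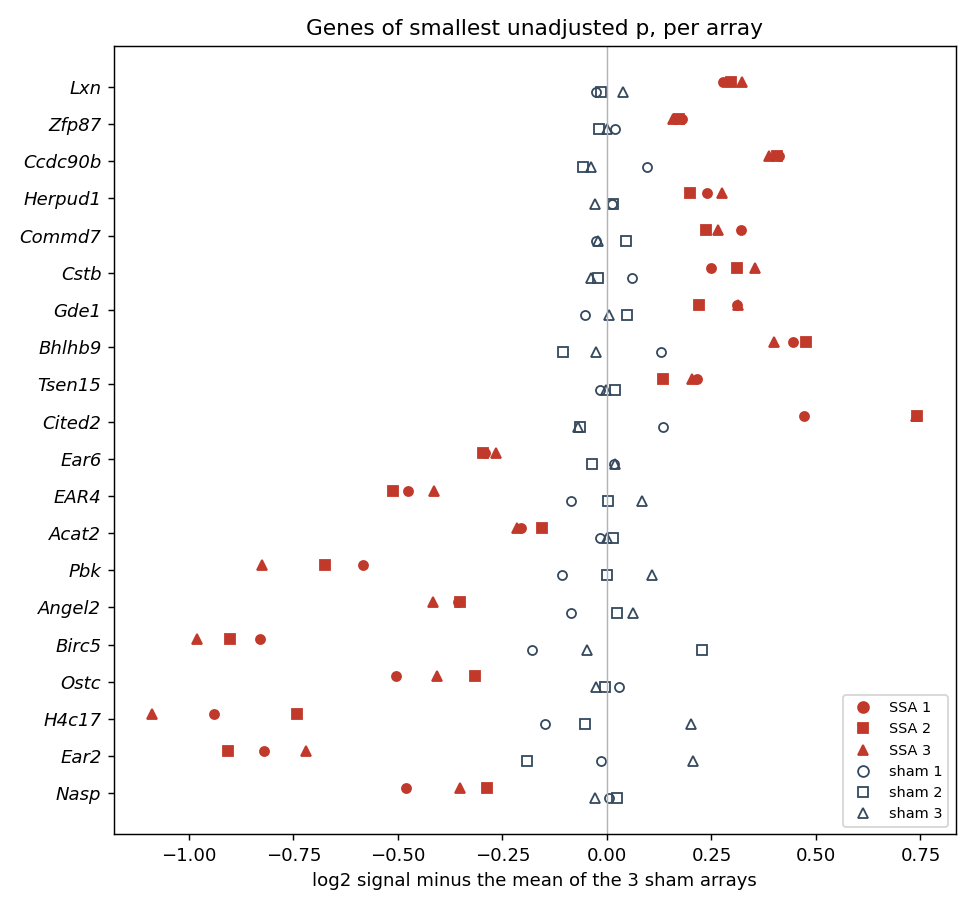
The horizontal axis gives log2 signal minus the mean of the 3 sham arrays for the 10 rises and 10 falls of smallest unadjusted p, and each symbol is 1 array. SSA arrays lie to the right of sham for Lxn to Cited2 and to the left for Ear6 to Nasp, and none of these genes passed the adjusted test.

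Transcripts of dividing cells were lower as a group after SSA. In the G2/M list, whose genes act in mitosis, 27 of 29 measured members were lower, with a median log2 fold change of -0.21, and camera gave an adjusted p of 2.02e-11. With an estimated correlation the adjusted p was 0.683, so the call was lost. Birc5 (-0.90) and the spindle checkpoint gene Mad2l1 (-0.55) passed limma when adjusted over the list alone, at 0.0161 and 0.0363, and none did over all genes. Top2a, a DNA topoisomerase, stood at -0.59 ± 0.13 and Cdca8 at -0.60 ± 0.14. Top2a was detected on 1 SSA array and 3 sham arrays. Of the genes for S phase and DNA replication, 40 of 42 were lower, with a median of -0.18 and an adjusted p of 7.44e-10 in camera, which became 0.683 with an estimated correlation. No member passed limma over all genes or adjusted over the list alone. Its members of smallest p were the helicase subunit gene Mcm7 at -0.50 ± 0.13, Rfc2 at -0.33 ± 0.090, Gins1 at -0.47 ± 0.14 and the thymidylate synthase gene Tyms at -0.29 ± 0.087. Tyms was detected on 1 SSA array and 3 sham arrays.

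For the G2/M list the median per array, relative to the mean of all 6, was -0.045, -0.064 and -0.20 on the SSA arrays and 0.013, 0.20 and 0.072 on the sham arrays. For S phase genes it was -0.088, -0.055 and -0.086 on the SSA arrays and -0.069, 0.19 and 0.17 on the sham arrays, so sham 1 lay with the SSA arrays. Both lists were called without any one array in turn, but without sham 2 the medians were -0.094 and -0.10, and without sham 1 the S phase median was -0.29. Over 19 settings the median ran from -0.44 to -0.080 for G2/M, smallest with no filter on dim genes, and from -0.29 to -0.10 for S phase genes. The detection-curve setting gave a median of -0.44 for G2/M, and -0.94, -0.70 and -0.55 for Top2a, Gins1 and Tyms. Immediate-early genes and neutrophil and monocyte genes were lower in the same comparison, with medians of -0.88 and -0.17. Erythroid genes, which were not called, stood lower in 9 of 9 members with a median of -0.38, but every member overlapped between the groups. The progenitor genes Mpo (-0.59) and Ctsg (-0.87) were lower on every SSA array than on every sham array. Prtn3, another progenitor gene, stood at 0.11, and the committed progenitor list was not called. Eosinophil ribonuclease genes stood lower too. The proliferation marker Mki67 was left out by the detection filter, although its raw signal was 371, 490 and 326 on the SSA arrays and 516, 524 and 754 on the sham arrays. With a filter on signal its log2 fold change was -0.46 ± 0.11, and it did not pass limma, at an adjusted p of 0.519. Ccnd1, a cyclin of the G1 phase, stood at 0.17 ± 0.33.

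**Figure D2:**
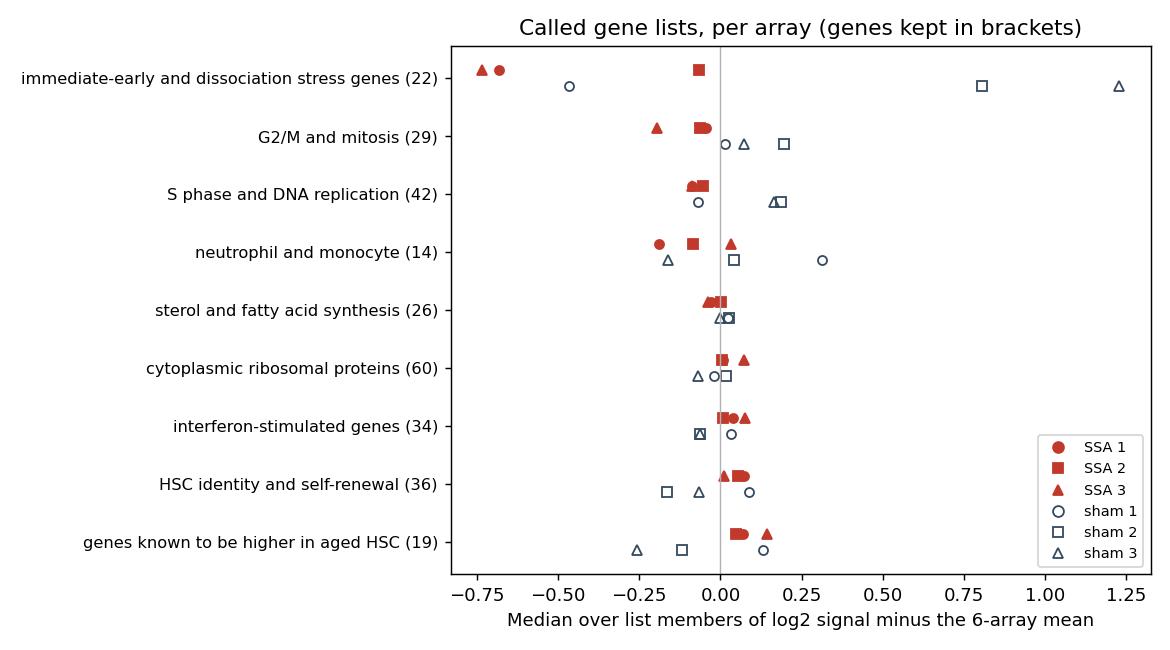
The horizontal axis gives, for each called list, the median over its genes of log2 signal minus the mean of the 6 arrays, and each symbol is 1 array. The G2/M medians of the SSA arrays lie between -0.20 and -0.045, below the sham arrays at 0.013 to 0.20, while for immediate-early genes sham 1 at -0.47 lies between SSA 1 and SSA 2.

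Immediate-early genes, which respond within minutes to stimuli and to tissue dissociation, had the largest median difference of the called lists. All 22 measured members were lower after SSA, with a median log2 fold change of -0.88 and an adjusted p of 4.97e-08 in camera. With an estimated correlation, the adjusted p was 0.683. No member passed limma, over all genes or adjusted over the list alone. None reached even an unadjusted p under 0.05 in limma, where the smallest was 0.0581, for Hspa1a. The phosphatase gene Dusp1 stood at 10.50 ± 1.36 in SSA and 12.48 ± 0.98 in sham (SD, n = 3). The heat shock genes Hspa1a and Hspa1b had log2 fold changes of -2.52 ± 1.03 and -1.46 ± 0.64, and Jund, a subunit of the AP-1 transcription factor, -0.18 ± 0.074. The median per array was -0.68, -0.066 and -0.73 on the SSA arrays and -0.47, 0.81 and 1.23 on the sham arrays. Without sham 1 the median fold change was -1.44 and without sham 3 it was -0.57. With no filter on dim genes it was -0.22, the weakest of 19 settings. The detection-curve setting gave a median of -1.48, and -2.93 and -1.57 for Hspa1b and Jund. Neutrophil and monocyte, erythroid and eosinophil ribonuclease genes stood lower in the same comparison.

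Genes that are known to be higher in aged HSC were higher as a group after SSA in these young adult animals. Of 19 measured members 17 were higher, with a median of 0.17 and an adjusted p of 0.000864 in camera, or 0.683 with an estimated correlation. Selp, the adhesion molecule P-selectin, stood at 1.41 ± 0.41 and the sulfotransferase gene Sult1a1 at 1.43 ± 0.58. Tgm2, a transglutaminase, stood at 0.66 ± 0.25 and Mllt3 at 0.17 ± 0.064. None of them passed limma, over all genes or adjusted over the list alone. Sult1a1, Tgm2 and Mllt3 are also members of the HSC identity list, so the results of these lists are not independent. The call was lost without sham 3, at a median of 0.084 and an adjusted p of 0.0819, in a range of 2.71e-08 to 0.0819 over 19 settings. The median per array was 0.069, 0.049 and 0.14 on the SSA arrays and 0.13, -0.12 and -0.26 on the sham arrays. As for S phase and immediate-early genes, sham 1 lay with the SSA arrays, so the difference came from sham 2 and sham 3. With no filter on dim genes the median was 0.040, the lowest of 19 settings, and the highest was 0.43, with the series matrix values. The detection-curve setting gave a median of 0.40, and 0.74 for Mllt3. Immediate-early, neutrophil and monocyte, erythroid and eosinophil ribonuclease genes stood lower in the same samples.

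In the list of HSC identity and self-renewal genes 24 of 36 members were higher, with a median of 0.075 and an adjusted p of 0.0396 in camera, or 0.757 with an estimated correlation. Hoxb5, a marker of long-term stem cells, stood at 0.61 ± 0.23, whereas the stem cell factor receptor gene Kit stood at -0.36 ± 0.082 and the transcription factor gene Tal1 at -0.49 ± 0.19. No member passed limma, over all genes or adjusted over the list alone. This call held without sham 1, with a median of 0.11, and was lost without each other array. The adjusted p was 0.135, 0.133 and 0.05002 without SSA 1, SSA 2 and SSA 3, and 0.720 and 0.0819 without sham 2 and sham 3, and 0.189 with the stricter filter on dim genes, in a range of 2.47e-05 to 0.720 over 19 settings. The medians without SSA 1 and sham 2 were 0.049 and 0.041, the detection-curve setting gave 0.23, and with no filter on dim genes the median was lowest, at 0.028. The median per array was 0.072, 0.053 and 0.010 on the SSA arrays and 0.088, -0.17 and -0.065 on the sham arrays, so sham 1 lay above every SSA array. Immediate-early, neutrophil and monocyte, erythroid and eosinophil ribonuclease genes stood lower in the same comparison. Of further members of the HSC identity list, Gata2 stood at -0.13 ± 0.16, Slamf1 at 0.028 ± 0.074 and Mecom at 0.019 ± 0.046. Vwf, a stem cell gene outside that list, stood at 0.33 ± 0.25. The cell cycle inhibitor Cdkn1c, which keeps stem cells quiescent and is a member of that list, stood at 0.95 ± 0.51. Cdkn1a, outside the list, stood at -0.054 ± 0.031. For Cdkn1a, Mecom and Slamf1 the detection-curve setting gave -0.42, 0.25 and 0.15.

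**Figure D3:**
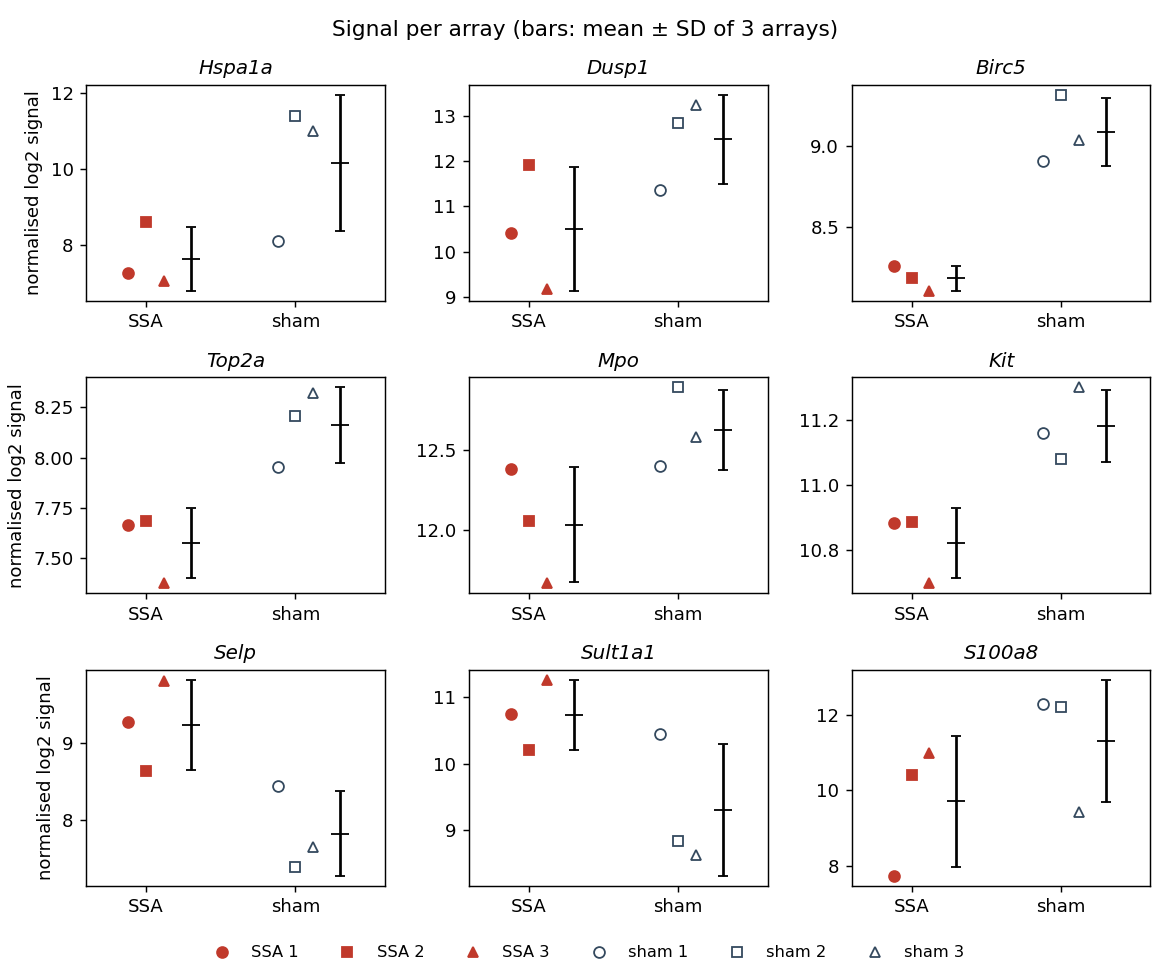
The vertical axis gives normalised log2 signal, each symbol is 1 array, and bars show the mean ± SD of 3 arrays per group. Birc5, Top2a, Mpo and Kit lie lower on all SSA arrays than on all sham arrays and Selp lies higher, while Hspa1a, Dusp1, Sult1a1 and S100a8 overlap between the groups.

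Sterol and fatty acid synthesis genes were lower as a group, by a small amount. Of 26 members 23 were lower, with a median of -0.023 and an adjusted p of 0.000864 in camera, or 0.683 with an estimated correlation. Acat2, an acetyl-CoA acetyltransferase, stood at -0.19 ± 0.024 and passed adjusted over the list alone, at 0.0119, and not over all genes. Ebp and Cyp51, both enzymes of cholesterol synthesis, stood at -0.29 ± 0.083 and -0.15 ± 0.061, and the regulator Srebf2 at -0.32 ± 0.13. The median was -0.038, -0.034 and -0.013 without SSA 2, sham 1 and sham 2, and -0.20 with the detection-curve setting, which gave -0.35 for Acat2 and -0.71 for Cyp51. Over 19 settings it ran from -0.23 to -0.013. Per array it was -0.029, 0.0014 and -0.037 on the SSA arrays and 0.022, 0.028 and -0.0015 on the sham arrays, so SSA 2 lay above sham 3. Neutrophil and monocyte, erythroid, immediate-early and eosinophil ribonuclease genes also stood lower in this comparison.

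Cytoplasmic ribosomal protein genes and interferon-stimulated genes were slightly higher as groups. Of the ribosomal protein genes 43 of 60 were higher, with a median of 0.048 and an adjusted p of 0.00508 in camera, or 0.683 with an estimated correlation. Rpl36a stood at 0.43 ± 0.088, Rplp0 at 0.20 ± 0.041, Rps15 at 0.20 ± 0.051 and Rpl12 at 0.17 ± 0.048. The ribosomal call was lost with the detection-curve setting, at 0.210, with normexp by maximum likelihood, at 0.0693, with the series matrix values, at 0.210, and without SSA 3 or sham 3, at 0.155 and 0.146, in a range of 6.54e-05 to 0.210 over 19 settings. Its median was 0.073 without sham 2 and 0.031 without sham 3, and 0.084 with array weights. Per array it was 0.0089, 0.0036 and 0.072 on the SSA arrays and -0.021, 0.016 and -0.069 on the sham arrays, so sham 2 lay above SSA 1 and SSA 2. While these genes were higher, neutrophil and monocyte, erythroid, immediate-early and eosinophil ribonuclease genes stood lower.

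Of the interferon-stimulated genes 27 of 34 were higher, with a median of 0.053 and an adjusted p of 0.00508 in camera, or 0.683 with an estimated correlation. The antiviral genes Bst2, Ifitm1, Mx2 and Oasl2 stood at 0.39 ± 0.14, 0.42 ± 0.17, 0.051 ± 0.022 and 0.55 ± 0.24. This call was lost without SSA 3 or sham 3, at 0.122 and 0.0819, in a range of 0.000285 to 0.122 over 19 settings, and its median was 0.084 without sham 1 and 0.22 with the detection-curve setting, which gave 0.47 for Mx2. The interferon median per array was 0.039, 0.0064 and 0.076 on the SSA arrays and 0.032, -0.064 and -0.063 on the sham arrays, so sham 1 lay among the SSA arrays. Over 19 settings the median ran from 0.018, with no filter on dim genes, to 0.24. Here too neutrophil and monocyte, erythroid, immediate-early and eosinophil ribonuclease genes stood lower. No member of either list passed limma, over all genes or adjusted over the list alone.

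Genes of the Foxo family and their targets were not called, at an adjusted p of 0.233, with a median of 0.036 and a mean of -0.017, which differ in sign, and a median of 0.14 in the detection-curve setting. Cited2 and the mitochondrial superoxide dismutase gene Sod2, at 0.65 ± 0.10 and 0.31 ± 0.055, passed adjusted over the list alone, both at 0.0186, and not over all genes. Pik3ip1 stood at 0.50 ± 0.16 and Irs2 at 0.072 ± 0.033. The unfolded protein response list was not called, at 0.689, and Herpud1 passed adjusted over the list alone, at 0.00584. Of its other members, Xbp1 stood at 0.35 ± 0.15, Trib3 at 0.21 ± 0.085 and the chaperone gene Dnajb11 at -0.29 ± 0.10. For Irs2 and Trib3 the detection-curve setting gave 0.45 and 0.84. In fry's test for change in either direction, these were the only pathway lists that passed, with adjusted p of 0.0416 and 0.0167.

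Lists of genes tied to steroid hormones were not called. Of the 61 measured androgen-response genes 29 were higher and 32 lower, with a median of -0.0027, or -0.0077 in the detection-curve setting, and an adjusted p of 0.569. The adjusted p was 0.326 for glucocorticoid-response genes and 0.569 for steroid hormone receptors and cofactors. The receptor genes Esr1 and Nr3c1 were detected on no array, with raw signals of 127.8 to 154.0 and 123.9 to 145.0. That does not show that they were not expressed, since Procr, a member of the HSC identity list, was also detected on no array. Fkbp5, a steroid-responsive co-chaperone gene, stood at -0.10 ± 0.11 and the glucocorticoid target Tsc22d3 at -0.082 ± 0.22. Cdkn1b, Flt3 and Procr did not pass the detection filter either, with raw signals between 128.9 and 151.8. Foxo1 and the brighter row of Foxo3 did not pass it at 159.9 to 210.5 and 159.5 to 219.1, and with a filter on signal their log2 fold changes were 0.010 ± 0.022 and -0.022 ± 0.027.

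The adjusted p was 0.0832 for myeloid priming, with a median of -0.041, and that list was called in the detection-curve setting at 0.0119, with a median of -0.14. With an estimated correlation that call was lost, at an adjusted p of 0.701. The adjusted p was 0.968 for lymphoid priming and 0.673 for megakaryocyte and erythroid priming. The Notch, Wnt, and TGF-beta and BMP pathways gave 0.951, 0.569 and 0.546, and niche adhesion and homing 0.548. HSC quiescence gave 0.437, NF-kB and inflammatory genes 0.546, p53 targets 0.983, where the test pointed down in the main and the detection-curve setting although the medians were 0.0071 and 0.025, and antioxidant genes 0.546. Oxidative phosphorylation gave 0.572 and glycolysis and hypoxia 0.447. None of the single genes fixed for these pathways passed limma, with Notch1 at 0.066 ± 0.17, Hes1 at -0.0072 ± 0.031, Cxcr4 at -0.025 ± 0.046, Ctnnb1 at 0.19 ± 0.093, Tgfbr1 at 0.016 ± 0.036 and Il7r at -0.0051 ± 0.016. For Notch1, Hes1, Cxcr4, Tgfbr1 and Il7r the detection-curve setting gave 0.21, -0.019, -0.080, 0.055 and -0.10.

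Transcripts typical of other marrow cells were also measured in the sorted samples. Of the 7 cell type lists tested, that of neutrophils and monocytes was called, with 12 of 14 members lower after SSA, a median of -0.17 and an adjusted p of 0.0387 in camera, or 0.616 with an estimated correlation. S100a8, an abundant neutrophil protein, was measured at 7.75, 10.41 and 10.98 on SSA arrays 1 to 3 and 12.28, 12.20 and 9.44 on sham arrays 1 to 3. The lysozyme genes Lyz1 and Lyz2 stood at 0.19 ± 0.18 and -0.10 ± 0.17. This call was lost without SSA 1, SSA 2 or sham 1, at 0.159, 0.0550 and 0.606, and also with cyclic loess, the stricter filter, the filter on signal, array weights and the replicate block, at 0.0656, 0.451, 0.0644, 0.767 and 0.0620, in a range of 2.20e-06 to 0.767 over 19 settings. Its median was -0.023 without sham 1, -0.30 without sham 3, -0.012 with array weights, -0.079 with no filter on dim genes and -0.84 with the detection-curve setting. The median per array was -0.19, -0.086 and 0.033 on the SSA arrays and 0.31, 0.043 and -0.16 on the sham arrays.

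Committed progenitor genes were not called, at 0.292, although the granule genes Mpo and Ctsg stood at -0.59 ± 0.22 and -0.87 ± 0.26, while another granule gene, Prtn3, stood at 0.11 ± 0.067. Erythroid genes gave 0.0705, with all 9 members lower and a median of -0.38, and were called in the detection-curve setting at 0.0282. With an estimated correlation that call was lost, at an adjusted p of 0.596. The erythroid median per array was -0.59, -0.0014 and 0.035 on the SSA arrays and -0.038, 0.34 and -0.0044 on the sham arrays. No erythroid member reached an unadjusted p under 0.05 in limma, and every one overlapped between the groups. Car1, Hba-a1 and Hbb-b1 stood at -0.59 ± 0.74, -0.38 ± 0.47 and -0.54 ± 0.43. B cell genes gave 0.345, with Ighm at 0.014 ± 0.73, H2-Ab1 at 0.19 ± 0.32 and Cd74 at 0.34 ± 0.40. T and NK cell genes gave 0.292, with Cd8b1, Nkg7 and Lck at -0.32 ± 0.16, -0.57 ± 0.19 and -0.045 ± 0.074. Megakaryocyte and platelet genes gave 0.419, with Mmrn1, Pf4 and Gp5 at 0.19 ± 0.33, 0.15 ± 0.50 and -0.068 ± 0.41. Endothelial genes gave 0.339, with Egfl7, Stab1 and Ly6c1 at 0.21 ± 0.24, -0.10 ± 0.11 and -1.07 ± 0.36. In that list Emcn (0.66) and Sox18 (0.14), named after their values were seen, passed adjusted over the list alone, at 0.0425 each. For Lck, Pf4 and Sox18 the detection-curve setting gave -0.10, 0.10 and 0.83.

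The list results rest on a preset correlation of 0.01 between genes. The estimated correlation within the called lists ran from 0.105 to 0.630, and with it none of the 26 pathway lists or 7 cell type lists was called.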

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

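The detection-curve setting and the filter on signal were chosen after the data were examined, and all other settings were planned, except that the detection-curve setting was also run with an estimated correlation. No gene was called in the main setting. Ear6 was called with normexp by maximum likelihood, the series matrix values, the detection-curve setting and array weights, 1 gene each, and with EAR4 as 2 genes with trend and robust variances. The number at an unadjusted p under 0.05, 852 in the main setting, was 452 with a median shift per array, 1827 with no filter on dim genes and 3054 with array weights. The count of 8 pathway lists became 0 with an estimated correlation, also with the detection-curve setting, 0 with directional fry and 2 with mixed fry. The count of 1 cell type list became 2 with no background correction, normexp by maximum likelihood, median shift, series matrix values, the detection-curve setting, no filter, and trend and robust variances. It became 0 with cyclic loess, the stricter filter, the filter on signal, array weights, both estimated-correlation settings and both fry tests. Leaving out 1 array gave 0 to 0 genes, 483 to 1520 genes at an unadjusted p under 0.05, 4 to 10 pathway lists and 0 to 3 cell type lists. The cause of these differences was not tested.

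Deviations of same-numbered arrays correlated at 0.50, -0.064 and -0.29, and those of differently numbered arrays at -0.61 to 0.48. With so few arrays per group, these values cannot show whether the replicate numbers pair the samples, and the labels do not say. With the number as a block 0 genes were called, 887 had an unadjusted p under 0.05, and 8 pathway lists and 1 cell type list were called, though the neutrophil and monocyte list missed at an adjusted p of 0.0620.

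Of the called lists none changed direction. Among named genes that were not called, 33 values of 19 genes had the opposite sign, all at adjusted p of 0.360 or more. With array weights these were 0.037 for Hes1, 0.020 for Cxcr4, 0.0067 for Il7r, -0.18 for Ighm, -0.086 for Egfl7, 0.041 for Gp5, 0.023 for Lyz2. Hes1 stood at 0.031 with the series matrix values. Leaving out 1 array gave log2 fold changes of -0.034 to 0.013 for Hes1, -0.059 to 0.012 for Cxcr4, -0.49 to 0.60 for Ighm, -0.26 to 0.26 for Gp5, -0.19 to 0.065 for Lyz2, -0.073 to 0.19 for Notch1, -0.015 to 0.057 for Mecom, -0.78 to 0.026 for Hba-a1, -0.12 to 0.0094 for Lck, -0.28 to 0.050 for Tsc22d3, -0.10 to 0.47 for H2-Ab1, -0.10 to 0.48 for Ccnd1, -0.0096 to 0.042 for Tgfbr1, -0.055 to 0.49 for Mmrn1, -0.038 to 0.10 for Slamf1, -0.19 to 0.010 for Stab1 and -0.22 to 0.65 for Pf4. Without 1 array the log2 fold changes of 40 of 98 named genes, none of them called, moved by over 1.5 times, such as Vwf at 0.084 to 0.55, Gata2 at -0.26 to -0.023, Cdkn1c at 0.61 to 1.47 and Ly6c1 at -1.45 to -0.82. Signals near background limit what the dim genes can show. No header named a BeadChip, so that block was not run.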

Other observations

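All tests of explanations in this part were chosen after the results were seen, as were the eosinophil list, written after the Ear genes were seen, and the genes named here.

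Genes of the eosinophil granule stood lower on every SSA array than on every sham array, although none was called. Prg2, which encodes the major basic protein of eosinophils, was measured at 9.22, 7.63 and 9.78 on SSA arrays 1 to 3 and 11.05, 10.87 and 11.30 on sham arrays 1 to 3, a log2 fold change of -2.20 ± 0.59. Epx, the eosinophil peroxidase, stood at -0.076 ± 0.020, or -0.90 with the detection-curve setting. Prg3 was detected on 0 SSA and 3 sham arrays, and its signal was at least 1.04-fold higher in sham. The detection-curve setting gave Prg3 a log2 fold change of -1.07, whose size is uncertain because the SSA signal was not detected. Together with Ear2, Ear6 and EAR4, 6 of the 13 listed markers passed the detection filter, Prg3 by the sham arrays alone, and for all 6 every SSA array lay below every sham array. None passed limma in the main setting, where the smallest adjusted p was 0.464.

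The log2 fold changes of 37 genes exceeded 1 in size. Among them Fos, an immediate-early transcription factor gene, was measured at 8.17, 11.99 and 7.55 on SSA arrays 1 to 3 and 10.65, 13.09 and 13.37 on sham arrays 1 to 3, a log2 fold change of -3.13 ± 1.47, and Egr1 stood at -2.27 ± 1.10. Ly6a, the stem cell antigen Sca-1, stood at 1.02 ± 0.42 and Ndn, a gene tied to stem cell quiescence, at 1.11 ± 0.50. None of these passed.

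A candidate explanation for the lower eosinophil granule genes is eosinophil RNA carried by the sham samples. Only 2 markers outside the Ear family, Prg2 and Epx, were detected on all 6 arrays, and within groups their correlation lay at percentile 86.98 of 10000 random pairs of similar signal. It was 0.977 among the SSA arrays and -0.667 among the sham arrays, and the percentile was 98.64 with Prg3, which was not detected in SSA. Shared hybridisation among Ear paralogs does not reach Prg2, and both Prg2 and Epx, 2 of 2, were lower with no overlap, but Epx lay near background and the Ear genes themselves stay open to it. With so few markers, these explanations and a change of these transcripts with SSA, which is untested, cannot be told apart.

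The lower cell cycle lists might follow handling of the samples, read by immediate-early genes, or more progenitor RNA in the sham samples. With the immediate-early score as a covariate the G2/M median went from -0.21 to -0.1513, and the S phase median from -0.18 to -0.037, with unadjusted camera p of 3.14e-11 and 0.00994 at the preset correlation and 0.125 and 0.377 at an estimated one. With the HSC identity score the medians were -0.121 and -0.064, at 1.17e-09 and 3.19e-05 preset and 0.158 and 0.114 estimated. Myeloid priming, megakaryocyte and erythroid priming and the first principal component were tried too, and gave G2/M medians of -0.062, -0.17 and -0.12 and S phase medians of -0.056, -0.15 and -0.064. In that order, 223, 1037 and 917 genes had an unadjusted p under 0.05 in limma, against 852 without a covariate. With the immediate-early and HSC identity scores the number was 298 and 843. The preset camera p was highest with myeloid priming, at 0.000138 for G2/M and 0.0423 for S phase. The preset p stayed under 0.05 with both tested scores. That cannot count against either cause, since the preset test called 58% of simulated draws without an effect at a correlation of 0.37. The HSC identity score is also no direct measure of progenitor genes. At an estimated correlation the lists missed even without a covariate, at 0.0729 and 0.156. Handling, progenitor RNA and SSA therefore cannot be told apart.

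Sham 1 lay nearer the SSA arrays. Over 1520 genes that differed when it was left out, its median position was 0.2152. The scale ran from the SSA mean at 0 to the mean of the other sham arrays at 1. Each other array was placed over its own 483 to 848 genes that differed without it. Left-out SSA arrays lay at 0.153, 0.524 and 0.353 and the other sham arrays at 0.682 and 0.880. A mislabelled array might give the position of sham 1, but its eosinophil granule genes were at sham levels, and since those were picked with its values the label stays open. Handling that immediate-early genes read is another candidate explanation. Across 1506 of the 1520 genes, immediate-early genes left out, SSA 2 minus the other SSA arrays correlated at -0.3518 with sham 1 minus the other sham arrays. These genes were picked for differing between the SSA arrays and the other sham arrays. On such genes the inward positions of SSA 2 and sham 1 tend by themselves to give a negative value, so it cannot decide. The bound for this correlation was set after a related value was seen, and genes are not independent. The deviations of these 2 arrays correlated at -0.049 over all genes, and cell makeup could give the same value.

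The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split called 0 genes against at most 1 in another, so all 10 splits, itself included, reached its count. It gave 852 genes at an unadjusted p under 0.05 against 1619 for SSA 1, SSA 2 and sham 1 against the rest, so 2 splits reached its count, itself and 1 other. It called 8 pathway lists against at most 11, with at least 8 in 2 splits, itself and 1 other. It called 1 cell type list against at most 4, with at least 1 in 8 splits, itself and 7 others.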
